A study of Mus musculus with 12 samples.

How the data were processed

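The samples were regulatory T cells from 4 wild-type mice. Per the labels' protocols, CD4+ cells carrying the Foxp3-Thy1.1 reporter were sorted as negative for an intravenously given CD45 antibody, which marks cells inside blood vessels, and negative for CD19, CD11b, CD8 and F4/80. The labels give this sort for all tissues, and how cells of blood, which such an antibody reaches, were gated is not stated. Cells of 5 tissues of each mouse (blood, liver, kidney, pancreas and small intestine) were marked with hashtag antibodies, pooled and loaded together for 10x Genomics 5' gene expression with T cell receptor sequencing. Each mouse thus gave 3 libraries, for gene expression, T cell receptor and antibody tags, and the mouse was at once the replicate, the block and the batch. The labels name the animal of each library, so the replicate numbers pair the 5 tissues of a mouse.

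Per the file headers and the submitters' processing notes, the authors made the matrices with Cell Ranger 5.0.0 against mm10, and Seurat is named as a tool without its version. The deposited values used here were raw UMI counts per feature and cell barcode from the filtered matrices, not normalized, with 32285 genes, 5 hashtags and 1 CD69 antibody tag in each matrix. The hashtags carried the names Blood, Pancreas, Kidney, Liver and LPL, and LPL was taken as small intestine because that was the tissue of the labels left without a tag. The deposited T cell receptor tables list assembled contigs with their chain, CDR3 sequences and read and UMI counts, as Cell Ranger wrote them, per the labels. All listed contigs were in called cells, productive and of high confidence. The deposited files hold no cell annotation, and the antibody tag libraries were deposited only as tag references, with their counts in the gene expression matrices. Gene identifiers and symbols were those paired in the feature files, and no genome sequence was used.

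The 4 matrices held 13414 barcodes, with 3068, 3641, 3962 and 2743 in mice 1 to 4. Their gene UMIs summed to 14104726, 17045373, 17441482 and 10872042. Hashtags were called per mouse with HTODemux of Seurat 5.3.0 (centred log ratio, positive quantile 0.99). Barcodes with 2 or more tags were left out as doublets (1375 barcodes, 10.3%), as were 93 without a tag. This step also served as the doublet filter, and doublets of 2 cells from the same tissue cannot be seen by it. Of 11946 singlets, those with at least 300 genes and at most 10% mitochondrial UMIs were used (11697 cells, 200 to 866 per mouse and tissue). A second rule, under which the top tag had to hold 80% of the tag counts of a cell and at least 10 counts, assigned no singlet to another tissue.

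Cells are not replicates. UMI counts were summed per mouse and tissue, which gave 20 sums of 647213 to 4455795 UMIs, and the sums were tested. Genes were kept with filterByExpr (10234 genes), and edgeR 4.0.16 was fitted with TMM factors and its quasi-likelihood F test, with tissue and mouse as terms over all 20 sums. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Contrasts were each tissue minus blood, the mean of the 4 tissues minus blood, and each non-blood tissue minus the mean of the other 3. Every adjusted p of a gene below is from this edgeR test unless another tool is named. Sums of the same mouse deviated together, with a mean correlation of deviations from the tissue means of 0.391 (lowest 0.123, over 4488 genes). Between mice it was -0.127, a value that centring on the tissue means itself pushes below 0. The mouse stayed in the fit as the block that the design had named. Values are given as CPM of the sums, as edgeR computes it with TMM factors, mean ± SD over 4 mice.

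Clones were built from cells with 1 productive TRB contig and at least 1 productive TRA contig (7628 cells). Cells of the same mouse with the same TRB V gene, TRB CDR3 nucleotides and top TRA CDR3 nucleotides formed a clone. An expanded clone had 2 or more cells in a mouse. UMIs were summed per mouse, tissue and clone class where both classes had at least 10 cells, and tested with mouse-by-tissue as the block (7147 genes for expanded against single-cell clones, 3253 for multi-tissue against single-tissue expanded clones, blood left out of the latter). In both contrasts the pairs of mouse and tissue come from 4 mice and can share clones, so they are not independent replicates. Clonal overlap of 2 tissues was the chance that a cell of each shares a clone, divided by the geometric mean of the chances that 2 cells within each tissue do. It is 0 without sharing and about 1 when tissues share clones as cells within a tissue do. It was compared with 10000 shuffles of the tissue labels within a mouse (one-sided). The share of cells in clones of 2 or more cells of the same tissue was computed after thinning all tissues of a mouse to the same number of cells (259, 232, 285 and 117 in mice 1 to 4; 200 draws). Differences over the 4 mice were tested with an exact two-sided sign-flip permutation test, whose smallest possible p is 0.13, and adjusted over 8 such tests.

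The gene lists, the contrasts and the alternatives not named as later were fixed before the data were examined. There were 16 lists of T cell programs and 9 lists of other cell types. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Lists with fewer than 3 tested genes were not tested. Members called are counted over all genes tested and also adjusted over the list alone. The named genes followed a rule fixed at the same time. For the mean of 4 tissues these were the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 5 and the same sign in every mouse. For each tissue against blood the first 4 of each direction were taken, for each tissue against the other tissues the first 6 rises and 4 falls, and for the clone contrasts the first 8 of each with the same sign in at least 3 mice. Receptor and immunoglobulin segments, haemoglobin, mitochondrial and ribosomal genes, unnamed gene models and members of the other-cell-type lists were left out of the ranking. Members of the lists, Foxp3 and Thy1 could be named in addition.

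Cells were also clustered (leidenalg 0.10.2 on a shared-neighbour graph built with scikit-learn 1.9.0), mainly to find cells of other types. In an alternative, 3 clusters led by genes of other cell types (117, 78 and 30 cells) were left out. The clusters of 117 and 30 cells had a TRB contig in 73.5% and 70.0% of cells, and Foxp3 at 219 and 149 CPM. They need not be other cell types. In the cluster of 78 cells these values were 29.5% and 34.3 CPM. The 4 tissues share the blood sums. Their overlap of calls was therefore set beside a simulation with blood and tissues all at the mean blood level. The overlap was also repeated with the blood of 2 mice for liver and kidney and of the other 2 mice for pancreas and small intestine.

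The gene test was checked on simulated counts with 200 changed genes. For the mean of 4 tissues against blood it recovered 64.2%, 85.1% and 97.0% of genes changed 1.5-, 2- and 4-fold among 10234 genes, and 5.20% of its calls were false. For liver against blood the shares were 53.7%, 86.6% and 98.5%, with 8.09% false calls. For expanded against single-cell clones they were 91.0%, 100% and 93.9% among 7147 genes. For multi-tissue against single-tissue clones they were 80.6%, 79.1% and 81.8% among 3253 genes, with 6.40% false calls. Apart from the changed genes, the simulated sums shared the same mean profile, with no mouse or tissue effect. These shares need not hold for the real sums. The list test gave a p under 0.05 in 8 of 200 random lists, and the overlap measure returned 0.4999 where 0.5 was simulated.

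Alternatives tried were DESeq2 1.42.0, DESeq2 size factors in edgeR, no mouse block, no low-count filter, a stricter cell filter (600 genes, 5% mitochondrial UMIs), the second hashtag rule, cells with a TRB contig only, sums thinned to the smallest total, each mouse left out in turn, other clone definitions and the other list tests. R 4.3.3, Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used. Reads were not analysed here, and neither index nor mapping rates enter the values.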

Results

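Regulatory T cells (Tregs) from blood, liver, kidney, pancreas and small intestine of 4 wild-type mice were profiled by single-cell RNA sequencing with paired T cell receptor sequences. Each mouse contributed all 5 tissues, so every comparison of tissues had n = 4 mice per tissue. After hashtag assignment and filtering, 11697 cells were used, of which 2334 were from blood, 2799 from liver, 2496 from kidney, 1365 from pancreas and 2703 from small intestine. The summed gene UMIs per mouse and tissue ranged from 647213 in a pancreas to 4455795 in a liver. The median UMIs per cell averaged 3447 ± 375 in blood, 4078 ± 420.3 in liver, 2860 ± 235 in kidney, 2980 ± 170 in pancreas and 3403 ± 298 in small intestine (SD, n = 4). A paired receptor was typed in 7628 cells. The share of cells with a TRB contig was 87.8% ± 3.47 in blood, 88.9% ± 2.58 in liver, 79.3% ± 4.61 in kidney, 79.4% ± 3.11 in pancreas and 70.0% ± 6.73 in small intestine (SD, n = 4).

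Foxp3, the lineage factor whose reporter was used for the sort, was present in every tissue, at 177 ± 28.1 CPM in blood, 197 ± 27.1 in liver, 179 ± 28.7 in kidney, 189 ± 19.9 in pancreas and 242 ± 30.1 in small intestine (SD, n = 4). The mean of the 4 tissues differed from blood by a log2 fold change of 0.18 (SE 0.07, adjusted p = 0.0463), a call that was lost without mouse 2, where the log2 fold change was 0.19, and without mouse 3, where it was 0.13. It was also lost without the mouse block (0.17), with cells that have a TRB contig alone (0.16), in thinned sums (0.10) and in cells low in stress genes (0.09). Thy1 fell, with a log2 fold change of -0.57 (SE 0.05, adjusted p = 4.73e-09); whether transcripts of the Thy1.1 reporter are counted under this gene was not tested.

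The first question was which genes separated tissue Tregs from those in blood, since the series title speaks of a residency program shared by tissues. Across the mean of the 4 tissues, immediate-early and residency-associated factors were among the largest rises. Nr4a1 (ENSMUSG00000023034), a nuclear receptor induced by T cell receptor signals, had a log2 fold change of 4.49 (SE 0.17, adjusted p = 6.99e-15). It went from 14.0 ± 2.32 CPM in blood to 28.9 ± 13.9 in liver, 451 ± 111 in kidney, 857 ± 128 in pancreas and 885 ± 57.5 in small intestine (SD, n = 4). Bhlhe40 (ENSMUSG00000030103), a transcription factor of resident T cells, rose by 4.34 (SE 0.15, adjusted p = 2.97e-15), and the chemokine receptor gene Ccr8 (ENSMUSG00000042262) by 4.53 (SE 0.22, adjusted p = 2.46e-13). The effector genes Areg and Il10 rose by 4.46 (SE 0.31, adjusted p = 8.06e-11) and 5.31 (SE 0.64, adjusted p = 5.87e-07). Il10 had 4 UMIs in all blood sums together, so the size of its fold change rests on those. Sell (ENSMUSG00000026581), which codes for the lymph node homing receptor CD62L, had a log2 fold change of -2.44 (SE 0.18, adjusted p = 1.50e-10), and S1pr4 (ENSMUSG00000044199), a receptor for the egress signal sphingosine 1-phosphate, of -1.53 (SE 0.07, adjusted p = 3.35e-14). These directions of the mean over tissues held in 4 of 4 mice for each of the genes. The remaining rises named by the rule were Hspa1a (log2 fold change 5.88), Hspa1b (4.74), Penk (4.53), Nr4a3 (4.43) and Nr4a2 (4.27), and the remaining falls were Igfbp4 (-2.46), Ly6c1 (-2.31), Lgals3 (-1.74), Il6ra (-1.62), Cmah (-1.57), Cdc25b (-1.45), Itgb1 (-1.42) and St8sia6 (-1.40). Hspa1a and Hspa1b are near-identical copies, and the split of counts between them is uncertain. In all, 3396 of 10234 genes were called by edgeR's quasi-likelihood test, with 1679 higher and 1717 lower in the tissues. The mean gives each tissue the same weight, and liver lay far closer to blood than the other 3 tissues did.

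**Figure D1:**
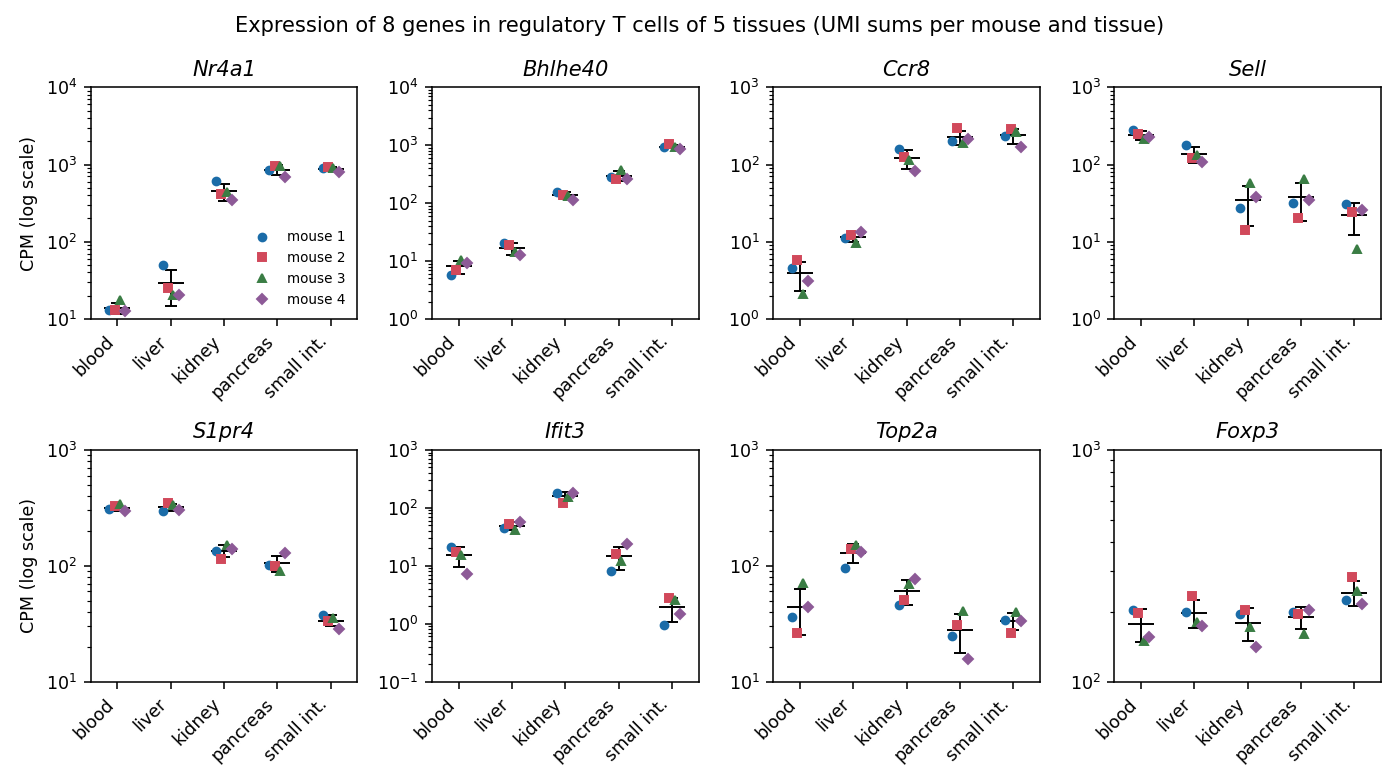
Expression of 8 genes in CPM (log axis) for blood, liver, kidney, pancreas and small intestine; points are mice 1 to 4 and black bars the mean and SD. Nr4a1 went from 14.0 ± 2.32 CPM in blood to 885 ± 57.5 in small intestine, while Top2a was highest in liver at 130.0 ± 23.8 and Ifit3 in kidney at 158 ± 29.0.

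By group, the tissue residency list was higher in the mean of the tissues, with a median log2 fold change of 1.90 over 26 genes and an adjusted p of 1.14e-25 (camera). Of its members 25 rose, 0 fell and 1 were not called (adjusted over the list alone 25 rose and 0 fell). Examples were Cd69 (1.10), Cxcr6 (1.73), Rgs1 (1.82) and Pdcd1 (3.12), and Itgae, which codes for CD103, was the member not called (-0.16 (SE 0.12, adjusted p = 0.353)). The T cell receptor activation list had a median of 2.01, and of its 23 members 22 rose, 0 fell and 1 were not called (adjusted over the list alone 22 rose and 0 fell), among them Tnfrsf9 (3.31). Tissue repair genes of the kind seen in ST2-positive Tregs had a median of 1.36, and 18 rose, 1 fell and 2 were not called (adjusted over the list alone 18 rose and 1 fell), with Gata3 at 1.01 and Il1rl1, the gene for ST2 itself, not called at 0.29 (SE 0.17, adjusted p = 0.205), though called without the low-count filter (0.31) and -0.64 in cells low in stress genes. Cytokine and suppressive effector genes had a median of 2.03 and costimulation genes of 1.30, with Ctla4 at 1.35. Intestinal peripheral Treg genes (1.15) and T helper lineage regulators (0.75) were also higher. Beside these, all 28 genes of the dissociation and heat shock list rose, with a median of 1.26 and an adjusted p of 1.14e-25, and the median share of UMIs from that list per cell was 0.701% ± 0.0407 in blood, 0.785% ± 0.0304 in liver, 1.57% ± 0.110 in kidney, 1.81% ± 0.127 in pancreas and 1.96% ± 0.110 in small intestine (SD, n = 4).

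Circulating and central T cell genes went the other way. All 18 members fell, with a median of -1.13, S1pr1 at -1.05 and Klf2 at -0.83 among them, and an adjusted p of 1.83e-12 (adjusted p = 0.0534 with an estimated correlation). Of 19 effector memory and migration genes 2 rose, 15 fell and 2 were not called (adjusted over the list alone 2 rose and 16 fell), with S100a4 at -1.22, a median of -0.77 and an adjusted p of 2.20e-08 (adjusted p = 0.17 with an estimated correlation). Chemokine receptors and integrins split, since 9 rose, 9 fell and 11 were not called (adjusted over the list alone 9 rose and 9 fell), with Ccr5 at 2.33 and Ccr10 at -2.69. Treg identity genes had a median of 0.32 and an adjusted p of 0.0123 (adjusted p = 0.348 with an estimated correlation), and glycolysis genes a median of 0.19 and an adjusted p of 0.0396 (adjusted p = 0.392 with an estimated correlation). Interferon response genes (median 0.12, test direction down, adjusted p = 0.934), cell cycle genes (median -0.00, test direction up, adjusted p = 0.9) and fatty acid and cholesterol genes (median 0.10, adjusted p = 0.527) were not called as lists, and for the first 2 of these the median and the test differed in sign.

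**Figure D2:**
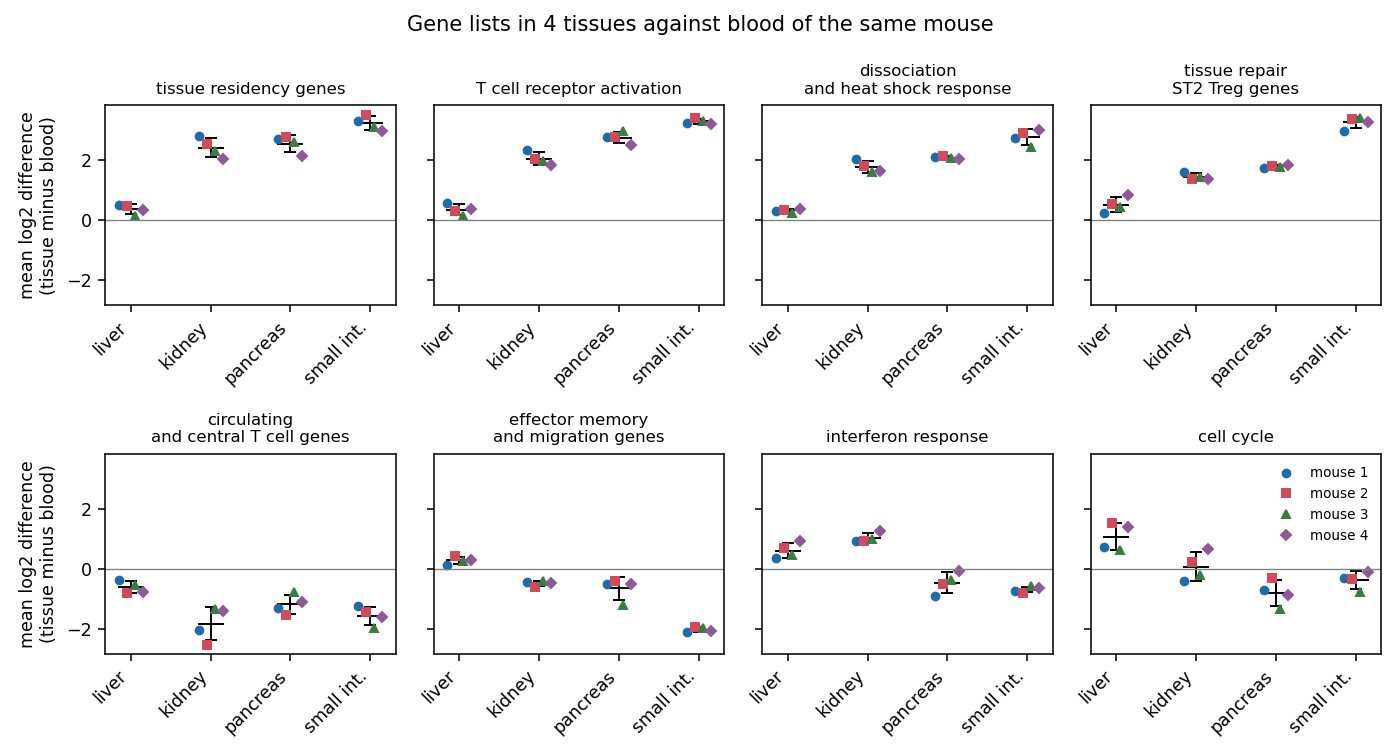
Mean log2 difference, tissue minus blood of the same mouse, of 8 gene lists in liver, kidney, pancreas and small intestine; points are mice 1 to 4 and bars the mean and SD. Residency genes went from 0.37 ± 0.17 in liver to 3.23 ± 0.24 in small intestine, while cell cycle genes were highest in liver at 1.07 ± 0.45.

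Genes of other cell types were checked as lists in the same contrast. Pancreas acinar and islet genes had a median of 1.95 and an adjusted p of 0.00129 (adjusted p = 0.429 with an estimated correlation), B and plasma cell genes of 1.64 with an adjusted p of 0.021 (adjusted p = 0.365 with an estimated correlation), and NK, CD8 and innate lymphoid genes, a list that shares members with Treg programs, of 1.01 with an adjusted p of 0.0106 (adjusted p = 0.09 with an estimated correlation). Small intestine epithelium genes (median 1.02, adjusted p = 0.171) and myeloid genes (median 0.10, adjusted p = 0.579) were not called. No kidney tubule gene passed the low-count filter, and 2 hepatocyte, 2 stroma and endothelium and 1 erythroid and platelet gene did, so these lists were not tested. The acinar gene Ctrb1 stood at 276 CPM in the liver sum of mouse 3, and at no more than 2.64 CPM in the liver of the other mice.

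Liver against blood asked how far liver Tregs differ from circulating ones. Proliferation genes rose, with Top2a, a DNA topoisomerase of dividing cells, at 1.59 (SE 0.15, adjusted p = 8.77e-07) and Mki67 at 1.03 (SE 0.13, adjusted p = 2.23e-05). Interferon-induced genes also rose, such as Isg15 at 1.29 (SE 0.18, adjusted p = 6.85e-05) and Ifit3 at 1.54 (SE 0.19, adjusted p = 1.72e-05). So did glycolysis genes such as Tpi1 at 1.07 (SE 0.11, adjusted p = 1.75e-06). Of 32 cell cycle genes 30 rose, 0 fell and 2 were not called (adjusted over the list alone 32 rose and 0 fell), with a median of 0.96 and an adjusted p of 2.81e-22. Of 29 interferon response genes 19 rose, 0 fell and 10 were not called (adjusted over the list alone 22 rose and 0 fell), with an adjusted p of 2.52e-14, and of 17 glycolysis genes 12 rose, 0 fell and 5 were not called (adjusted over the list alone 15 rose and 1 fell), with an adjusted p of 2.90e-11. Of 26 residency genes 9 rose, 2 fell and 15 were not called (adjusted over the list alone 12 rose and 2 fell), with a median of 0.48 and an adjusted p of 2.71e-05 (adjusted p = 0.212 with an estimated correlation). Cd69 was not called at 0.10 (SE 0.11, adjusted p = 0.602). Central T cell genes had a median of -0.69 and an adjusted p of 7.15e-08 (adjusted p = 0.152 with an estimated correlation).

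The genes named by rule for liver against blood were Hspa1a (3.06), Cxcl10 (2.72 (SE 0.54, adjusted p = 0.00215)), Hspa1b (2.54) and Cdkn1a (1.85) among the rises, and Ccr9 (-2.11 (SE 0.52, adjusted p = 0.011)), Bcl2 (-1.27 (SE 0.17, adjusted p = 6.87e-05)), Tnfsf8 (-1.18) and Tbc1d4 (-1.08) among the falls. Acinar genes had a median of 2.43 with an adjusted p of 0.00725 (adjusted p = 0.431 with an estimated correlation), but this rested mostly on mouse 3, with a mean log2 difference of 3.18 against -0.12, 0.50 and 0.16 in the others. A total of 1105 genes were called, 698 higher and 407 lower. The count was 479 in a fit without the mouse block, 347 without mouse 2 and 573 without mouse 4. Without mouse 2, Cxcl10 (2.09) and Ccr9 (-1.85) kept their sign and were no longer called, and in thinned sums the same held for Hspa1b (2.81), Cdkn1a (1.82), Ccr9 (-2.10) and Tbc1d4 (-0.63). Nr4a1 and Bhlhe40 were called higher in liver, but not without mouse 2 (1.02 and 0.93) or in thinned sums (0.89 and 0.98). In cells low in stress genes they were at 0.15 and 1.02 and not called.

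Kidney against blood called 2766 genes, 1371 higher and 1395 lower. Nr4a1 rose by 5.01 (SE 0.19, adjusted p = 9.94e-15), Nr4a2 by 4.94, Hspa1a by 6.16 and the chemokine gene Cxcl10 by 5.04 (SE 0.44, adjusted p = 5.88e-09). Sell fell, with a log2 fold change of -2.79 (SE 0.25, adjusted p = 1.05e-08), as did Igfbp4 (-3.60), Ly6c1 (-2.64) and Nsg2 (-2.28). Of 26 residency genes 25 rose, 1 fell and 0 were not called (adjusted over the list alone 25 rose and 1 fell), with a median of 2.44 and an adjusted p of 2.36e-28. All 18 central genes fell, with a median of -1.63 and an adjusted p of 7.56e-17. Interferon response genes had a median of 0.75 and an adjusted p of 7.59e-12 (adjusted p = 0.0641 with an estimated correlation). The dissociation list had a median of 1.28.

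Pancreas against blood called 2874 genes, 1429 higher and 1445 lower. The largest rises named were Il10 (6.33 (SE 0.51, adjusted p = 1.57e-09)), Nr4a1 (5.95 (SE 0.18, adjusted p = 6.92e-17)), Ccr8 (5.80) and Nr4a2 (5.49), and the falls Sell (-2.66 (SE 0.29, adjusted p = 1.81e-07)), Ccnb2 (-2.49), Gzmb (-2.13 (SE 0.47, adjusted p = 0.00139)) and Igfbp4 (-2.07). Gzmb was no longer called under the second hashtag rule, at -0.82. In cells low in stress genes, Il10 (3.13), Ccnb2 (-4.33), Gzmb (-3.48) and Igfbp4 (-0.57) were not called. All 23 T cell receptor activation genes rose, with a median of 2.40, and of 26 residency genes 21 rose, 1 fell and 4 were not called (adjusted over the list alone 22 rose and 1 fell). The dissociation list had a median of 1.70. Interferon response genes were lower, with a median of -0.62 and an adjusted p of 7.28e-07 (adjusted p = 0.17 with an estimated correlation). Acinar and islet genes had a median of 3.06 and an adjusted p of 7.28e-07 (adjusted p = 0.216 with an estimated correlation).

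Small intestine differed most from blood by number of calls, with 5375 genes, 2679 higher and 2696 lower. Il10 rose by 9.54 (SE 0.30, adjusted p = 1.66e-17), Hspa1a by 9.39, Hspa1b by 7.90 and Lilr4b, which has near-identical copies, by 7.13. The integrin chain gene Itgb1 fell, with a log2 fold change of -4.31 (SE 0.10, adjusted p = 3.06e-19), with Ly6c1 at -4.37, Lgals3 at -4.03 and S100a4 at -3.78. Of 26 residency genes 25 rose, 0 fell and 1 were not called (adjusted over the list alone 25 rose and 0 fell), with a median of 3.30, and of 20 intestinal peripheral Treg genes 16 rose, 2 fell and 2 were not called (adjusted over the list alone 17 rose and 2 fell), with a median of 2.71. The dissociation list had a median of 1.95 with all 28 members called. Effector memory and migration genes had a median of -2.0 and an adjusted p of 1.23e-10 (adjusted p = 0.13 with an estimated correlation). B and plasma cell genes had a median of 3.11 and an adjusted p of 0.00351 (adjusted p = 0.217 with an estimated correlation).

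The same direction was called in all 4 tissues against blood for 209 genes, 102 higher and 107 lower. Because the tissues share the blood sums, sums of blood and tissues were all simulated at the mean blood level. The highest count in 20 simulations was 0. With no gene changed few calls arise in any tissue, so this cannot show how far the shared blood raises the count. Independent lists of these sizes would share 5.48 genes. With the blood of different mice for liver and kidney than for pancreas and small intestine, the count was 75, of which 70 were among the 209. The count was 103 in a fit without the mouse block, 62 without mouse 2, 101 without mouse 4, 132 with the stricter cell filter, 70 in thinned sums and 16 in cells low in stress genes. Liver had the fewest calls of the 4.

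Each tissue was then set against the mean of the other 3, a contrast in which 1 of the 3 can decide the difference. In liver Tregs, cell division genes and Lgals3 were higher, while the factors that marked the other tissues were lower. Lgals3, a galectin, rose by 2.91 (SE 0.19, adjusted p = 7.21e-12) and Ccnb2 by 2.42 (SE 0.18, adjusted p = 8.29e-11), with Ube2c (2.41), Ccna2 (2.41), Birc5 (2.37) and Hist1h1b (2.34) beside them. Il10 had a log2 fold change of -6.13 (SE 0.33, adjusted p = 3.97e-13), Areg of -5.05, Nr4a1 of -4.64 (SE 0.15, adjusted p = 5.81e-17) and Nr4a2 of -4.49. Of 32 cell cycle genes 30 rose, 1 fell and 1 were not called (adjusted over the list alone 30 rose and 1 fell), with a median of 1.73 and an adjusted p of 1.13e-12 (adjusted p = 0.0952 with an estimated correlation). Of 26 residency genes 1 rose, 24 fell and 1 were not called (adjusted over the list alone 1 rose and 24 fell), with a median of -2.53. All 28 dissociation genes fell, with a median of -1.37. Effector memory and migration genes had a median of 1.52 and an adjusted p of 3.94e-11 (adjusted p = 0.102 with an estimated correlation). The contrast called 5346 genes, 2669 higher and 2677 lower.

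In kidney Tregs, interferon-induced genes were higher than in the mean of the other 3 tissues. Ifit3 (ENSMUSG00000074896) rose by 3.80 (SE 0.14, adjusted p = 9.27e-15), at 158 ± 29.0 CPM in kidney, 49.0 ± 7.26 in liver, 14.8 ± 6.54 in pancreas, 1.94 ± 0.862 in small intestine and 15.1 ± 5.70 in blood (SD, n = 4). Ifit1 (2.34), Cmpk2 (2.04) and Ifit1bl1 (1.99) followed. Ifit3 and Ifit1 have close copies, and the split of counts with these is uncertain. All 29 interferon response genes rose, with a median of 1.11 and an adjusted p of 5.35e-36, among them Irf7 at 1.21 and Stat1 at 0.44. Minus blood, this list had a mean log2 difference of 1.03 in kidney and 0.61 in liver, against -0.46 in pancreas and -0.69 in small intestine. Liver was thus raised too. A cluster led by Ifit3 held 13.4% of kidney cells and 12.6% of liver cells. The chemokine receptor gene Cxcr3 rose by 1.61 (SE 0.09, adjusted p = 1.66e-11) and Egr1 by 2.23 (SE 0.20, adjusted p = 2.03e-08). In cells low in stress genes, Egr1 was -0.78 and not called, and calls were also lost for Ifit1 (1.33), Isg15 (0.68) and Stat1 (0.21), and for Epas1 (-0.63), Dhrs3 (-1.84) and Ccr7 (-1.30) named below. Residency genes had a median of 0.41 and an adjusted p of 0.00156 (adjusted p = 0.325 with an estimated correlation), with Itga1 at 1.55 and Xcl1 at 3.09. Minus blood the mean log2 difference of residency genes was 2.42 in kidney, lower than in small intestine (3.23) and pancreas (2.56). It was higher only than in liver (0.37). The falls named were Epas1 (-2.53 (SE 0.34, adjusted p = 9.89e-06)), Dhrs3 (-1.91), Ramp3 (-1.82) and Ccr7 (-1.56). The first 3 were no lower in kidney than in liver (Epas1 1.56 against 1.46 CPM, Dhrs3 4.26 against 2.33 and Ramp3 14.6 against 11.1) and high in small intestine, at 160.5, 131 and 387 CPM. Of 1777 genes called, 799 were higher and 978 lower, and 1161 were called without mouse 2. In cells low in stress genes the balance turned, with 68.3% of the calls rises.

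In pancreas Tregs, T cell receptor activation genes were higher and division and interferon genes lower than in the mean of the other 3 tissues. Not all of this was particular to pancreas. T cell receptor activation genes minus blood had a mean log2 difference of 2.75 in pancreas and of 3.30 in small intestine, which was higher in each mouse, and Nr4a1 stood at 857 and 885 CPM. Interferon response genes minus blood had a mean log2 difference of -0.69 in small intestine and of -0.46 in pancreas. Nr4a1 rose by 1.95 (SE 0.10, adjusted p = 1.63e-11), Fosb by 2.07 (SE 0.18, adjusted p = 3.54e-08), Egr2 by 2.39 (SE 0.20, adjusted p = 1.25e-08) and Ramp1, part of a neuropeptide receptor, by 1.85 (SE 0.15, adjusted p = 7.80e-09). Egr3 (2.54), Rgs16 (1.77), Fos (1.75) and Dusp1 (1.73) also rose. Fosb, Fos and Dusp1 belong to the dissociation list, whose median was 0.58, and in cells low in stress genes Fosb (0.21) and Ramp1 (1.61) were not called, nor were 2 falls named below, Mki67 (-0.89) and Isg15 (-1.18). Gzmb had a log2 fold change of -4.60 (SE 0.34, adjusted p = 1.91e-09), Ccnb2 of -2.18 and Ube2c of -1.98. Defa21 (-2.02), a Paneth cell gene with close copies, was decided by mouse 4 and could not be tested without it, and it was not called by DESeq2 (-0.60). Of 23 T cell receptor activation genes 16 rose, 1 fell and 6 were not called (adjusted over the list alone 19 rose and 1 fell), with an adjusted p of 2.87e-12 (adjusted p = 0.0635 with an estimated correlation). Of 29 interferon response genes 0 rose, 26 fell and 3 were not called (adjusted over the list alone 0 rose and 27 fell), with Isg15 at -1.30 and an adjusted p of 2.73e-19 (adjusted p = 0.0635 with an estimated correlation). Of 32 cell cycle genes 0 rose, 23 fell and 9 were not called (adjusted over the list alone 0 rose and 26 fell), with Mki67 at -1.54 and an adjusted p of 2.08e-14 (adjusted p = 0.129 with an estimated correlation). Acinar and islet genes had a median of 1.45, with Clps at 2.21. In all 1570 genes were called, 746 higher and 824 lower, and 1006 without mouse 3.

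Small intestine Tregs carried the gut-homing receptor gene Ccr9, which rose by 5.24 (SE 0.17, adjusted p = 2.18e-17), and the hypoxia-inducible factor gene Epas1 (ENSMUSG00000024140), which rose by 6.37 (SE 0.13, adjusted p = 2.89e-21) to 160.5 ± 28.9 CPM (SD, n = 4). Il10 rose by 5.64 (SE 0.14, adjusted p = 1.03e-19) and Gzmb by 5.08 (SE 0.16, adjusted p = 8.52e-18). The lineage regulators Maf (1.42 (SE 0.05, adjusted p = 9.77e-17)) and Rorc (1.81 (SE 0.21, adjusted p = 8.73e-08)) rose, as did Gata3 (1.14), Areg (3.39), Tnfrsf9 (3.33), Gzma (6.98), Il17a (5.89) and Dgat1 (2.99), while Tbx21 (-1.69) and Cxcr3 (-2.53) fell. The sums mix groups of cells with their levels per cell, and these genes need not rise in the same cells. A cluster led by Gzma, with 35.2% of small intestine cells, had Il1rl1 at 205 CPM and Rorc at 4.20. Another, led by Ccl20 and Il17a, held 20.2% of them, with Il1rl1 at 6.14 CPM and Rorc at 114. All 21 tissue repair genes rose, with a median of 1.42. Of 20 intestinal peripheral Treg genes 16 rose, 2 fell and 2 were not called (adjusted over the list alone 16 rose and 2 fell), with a median of 1.87. Of 19 effector memory and migration genes 0 rose, 17 fell and 2 were not called (adjusted over the list alone 0 rose and 17 fell), with Itgb1 at -3.85, S100a4 at -3.41 and an adjusted p of 3.17e-12 (adjusted p = 0.0796 with an estimated correlation). Interferon response genes had a median of -0.86 and an adjusted p of 5.05e-11 (adjusted p = 0.0748 with an estimated correlation), with Ifit3 at -4.46 and Ifit1bl1 at -3.25. Hspa1a rose by 4.68, and it was 0.99 and not called in cells low in stress genes, where Tbx21 (-2.38) was not called either.

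Beside these genes stood transcripts of other cells in the small intestine. All 7 tested epithelium genes rose, with a median of 6.51 and an adjusted p of 0.019 (adjusted p = 0.375 with an estimated correlation), and 3.09 was the median of B and plasma cell genes, with an adjusted p of 0.00606 (adjusted p = 0.265 with an estimated correlation). Defa21 (6.15) stood at 1339 CPM in the small intestine of mouse 4 and at no more than 0.958 CPM in the other mice, and Lyz1 (6.82) at 1415 CPM in that sum. In cells with a TRB contig alone, Defa21 was -0.31 and Lyz1 -0.14 and neither was called. The contrast called 5336 genes, 2795 higher and 2541 lower.

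The list tests were repeated with an estimated correlation between genes. Of the list calls made, 7 of 16 held in liver against blood, 8 of 12 in kidney, 7 of 15 in pancreas, 8 of 16 in small intestine and 8 of 15 in the mean of the tissues. Against the other tissues, 7 of 14 held in liver, 2 of 10 in kidney, 0 of 13 in pancreas and 6 of 14 in small intestine. The residency, T cell receptor activation, dissociation and tissue repair lists held in the mean and in kidney, pancreas and small intestine against blood. In liver against blood, the cell cycle, interferon, glycolysis and tissue repair lists held together with those of intestinal peripheral Tregs, cytokines and T helper regulators. In kidney against the other tissues, the interferon list and the intestinal peripheral Treg list held. The latter list minus blood had a mean log2 difference of 0.74 in kidney, far below the 2.96 in small intestine. It was 0.51 in pancreas and 0.33 in liver.

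Receptor sequences were used to ask how far clones spread over tissues, since the title also speaks of migration between tissues. The 7628 typed cells formed 6238 clones, of which 682 had 2 or more cells. Of these, 372 were seen in 2 or more tissues, 72 in 3 or more, 10 in 4 or more and 2 in all 5. Per mouse, 54.0% ± 7.79 of multi-cell clones were in 2 or more tissues (SD, n = 4), against 85.5% when tissue labels were shuffled among the cells of a mouse. The normalized overlap averaged 0.239 ± 0.0440 over pairs of tissues (SD, n = 4 mice), while shuffled labels gave 1.05 on average. In each of the 4 mice none of 10000 shuffles was as low (one-sided permutation p = 0.0001, the smallest they can give). Identical receptors between mice, as a background, gave a mean overlap of 0.00846 for different tissues of 2 mice. Over all cells of 2 mice, tissues pooled, it was 0.0371, between 0.0032 and 0.0571 over 6 pairs of mice.

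Blood and liver shared the most, with an overlap of 0.906 ± 0.0820 (147 shared clones). Next were liver and kidney at 0.410 ± 0.134 (146 clones), blood and kidney at 0.345 ± 0.173 (73 clones), kidney and pancreas at 0.208 ± 0.101 (59 clones), liver and pancreas at 0.180 ± 0.0455 (45 clones) and blood and pancreas at 0.15 ± 0.0593 (20 clones). The 4 pairs with small intestine were lowest, at 0.0539 ± 0.0207 with blood (16 clones), 0.0388 ± 0.0357 with liver (13 clones), 0.0548 ± 0.0168 with kidney (21 clones) and 0.0433 ± 0.0186 with pancreas (14 clones), against 0.0013, 0.00049, 0.00158 and 0.00072 for the same pairs of tissues taken from different mice. Pairs with intestine were lower than those without in 4 of 4 mice (mean difference -0.319 ± 0.0605), and blood and liver exceeded blood and intestine in 4 of 4 (0.852 ± 0.0845). Kidney shared less with pancreas than with blood in 4 of 4 mice (-0.137 ± 0.0927). Each of these 3 differences had a two-sided exact sign-flip p of 0.13, the smallest that this test can give with 4 mice, and an adjusted p of 0.143, so none could pass 0.05 in it.

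**Figure D3:**
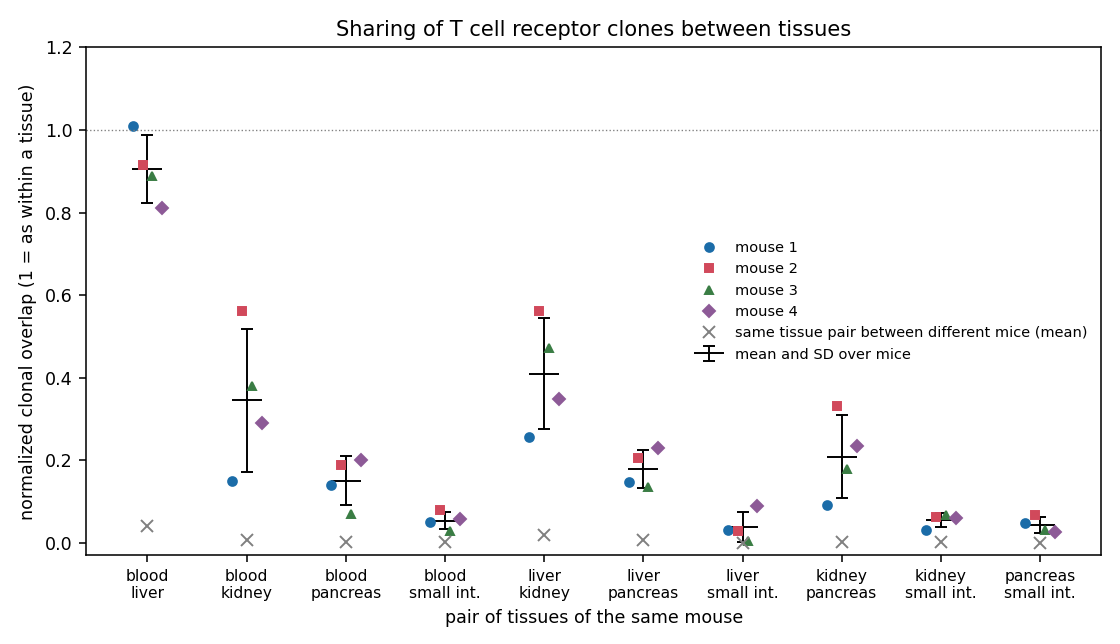
Normalized clonal overlap (no unit, 1 means shared as within a tissue) for the 10 pairs of tissues; points are mice 1 to 4, bars the mean and SD, and crosses the same pair of tissues taken from different mice. Blood and liver lie at 0.906 ± 0.0820, and the 4 pairs with small intestine lie between 0.0388 and 0.0548.

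At equal cell numbers, the share of cells in clones of 2 or more cells in the same tissue was 9.66% ± 2.70 in blood, 13.7% ± 1.40 in liver, 15.6% ± 3.55 in kidney, 13.7% ± 6.54 in pancreas and 14.3% ± 5.17 in small intestine (SD, n = 4). The difference from blood was 4.03 ± 1.53 percentage points in liver, 5.96 ± 4.70 in kidney and 4.67 ± 3.80 in small intestine, each above 0 in 4 of 4 mice (two-sided exact sign-flip p = 0.13, adjusted p = 0.143). In pancreas it was 4.02 ± 8.43, above 0 in 3 of 4 mice (exact p = 0.375). None passed the threshold, which this exact test cannot reach with 4 mice.

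**Figure D4:**
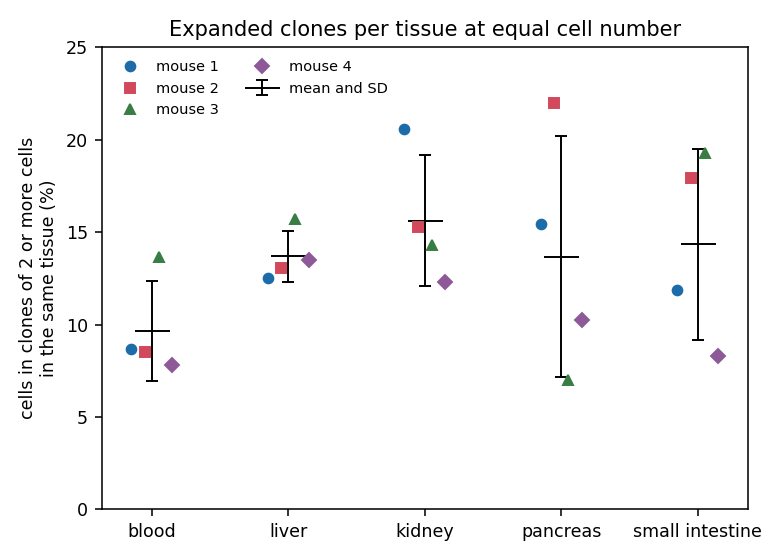
Percent of receptor-typed cells in clones of 2 or more cells of the same tissue, for 5 tissues at equal cell number within a mouse; points are mice 1 to 4 and bars the mean and SD. Blood was lowest at 9.66% ± 2.70 and kidney highest at 15.6% ± 3.55.

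Cells of expanded clones were compared with single-cell clones of the same mouse and tissue. The pairs of mouse and tissue came from 4 mice, and a clone seen in several tissues entered several pairs. The test took the pairs as independent, so the p-values of this contrast can be too small. Expanded cells had more of the effector and tissue repair genes and less of the central ones. Klrg1 (ENSMUSG00000030114), a marker of terminally differentiated Tregs, rose by 0.94 (SE 0.13, adjusted p = 2.58e-06), Il1rl1 by 0.91 (SE 0.11, adjusted p = 3.73e-07), Areg by 0.90 (SE 0.10, adjusted p = 3.19e-08) and Gzmb by 0.96 (SE 0.14, adjusted p = 7.20e-06). Igfbp4 had a log2 fold change of -6.08 (SE 0.32, adjusted p = 1.91e-16), Ccr7, a receptor for entry to lymph nodes, of -2.49 (SE 0.12, adjusted p = 2.98e-17) and Sell of -1.54 (SE 0.16, adjusted p = 9.72e-09). The other named rises were Anxa1 (1.11), Nav2 (0.87), Ctla2a (0.81) and Lmna (0.81), and the other falls Nsg2 (-2.95), Bcl2 (-2.32), Actn1 (-1.72), Ift80 (-1.58) and Ecm1 (-1.41). Not all of these differences were the same in every tissue. Set against the difference in the other tissues, that of Bcl2 was -2.52 in blood, -2.35 in liver, 2.13 in kidney and 2.17 in pancreas, that of Sell 3.43 in liver and 3.72 in kidney, and that of Areg 0.81 in pancreas. In blood it was 1.28 for Klrg1, 1.27 for Lmna, -1.67 for Ecm1, 0.72 for S100a4 and 0.92 for Lgals3, and for Gata3 it was -0.47 in liver and 0.60 in pancreas (each with an adjusted p under 0.05 for the interaction term in edgeR). Of 16 central T cell genes 1 rose, 13 fell and 2 were not called (adjusted over the list alone 1 rose and 14 fell), with Tcf7 at -1.16 and an adjusted p of 6.38e-16. Of 19 effector memory and migration genes 17 rose, 0 fell and 2 were not called (adjusted over the list alone 17 rose and 0 fell), with S100a4 at 0.65 and Lgals3 at 0.68, and of 20 tissue repair genes 14 rose, 0 fell and 6 were not called (adjusted over the list alone 14 rose and 0 fell), with Gata3 at 0.53. The adjusted p of these lists was 6.67e-18 and 2.70e-14, and 7 of 11 list calls in this contrast held with an estimated correlation. Residency genes had a median of 0.26 and an adjusted p of 2.57e-04 (adjusted p = 0.0623 with an estimated correlation), with Itgae at 0.79 and Cxcr6 at 0.70, and Cd69 was not called (-0.01 (SE 0.07, adjusted p = 0.973)). The T cell receptor activation list (adjusted p = 0.431) and the dissociation list (adjusted p = 0.282) were not called. In all 964 of 7147 genes were called, 564 higher and 400 lower. Without the low-count filter the balance turned, with 38.8% of the calls rises. The count was 607 without mouse 1, 567 without mouse 2 and 608 without mouse 3, and Lgals3 was not called by DESeq2 (0.53).

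Within expanded clones outside blood, cells of clones seen in several tissues were compared with cells of clones seen in 1 tissue. No gene of 3253 passed in edgeR's quasi-likelihood test, with 232 genes at an unadjusted p under 0.05, and DESeq2 called 1. The count was 2 without mouse 1, 7 without mouse 4, 2 in a fit with mouse and tissue as separate terms and 117 without the low-count filter. Activation genes leaned lower in multi-tissue clones without being called, with Tnfrsf9 at -0.85 (SE 0.20, adjusted p = 0.0943), Cd83 at -0.79 (SE 0.15, adjusted p = 0.0632), Dusp4 at -0.77 and Rel at -0.59, and S100a6 (0.46) and Klf3 (0.66) leaned higher. Without the low-count filter all 6 were called, and Cd83 was also called without mouse 1 (-0.88) and without mouse 4 (-0.82). As a list, T cell receptor activation had a median of -0.27 and an adjusted p of 2.14e-05 (adjusted p = 0.171 with an estimated correlation), with 0 members rising and 9 falling when adjusted over the list alone. Effector memory and migration genes had a median of 0.20 and an adjusted p of 3.08e-06 (adjusted p = 0.179 with an estimated correlation). Of 6 list calls in this contrast 0 held with an estimated correlation.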

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

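The tests on TRA chains, cell barcodes, the same tissue in different mice and cell cycle genes in this part were chosen after the results were seen, and the settings with cells low in stress genes and with a 95% hashtag share were added after the files were seen.

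Among 135 groups of 4 mice, 3 had a mouse far from the other 3, and chance gives about 1 in 20. The share of blood cells in expanded clones was 13.7% in mouse 3 (8.70%, 8.49% and 7.78% in the others). The median count of the CD69 antibody tag in blood was 64 in mouse 1 and 9, 14 and 13 in the others, while Cd69 transcripts in the same blood sum, at 118 CPM, were within the range of the other mice. Effector memory and migration genes in pancreas minus blood had a mean log2 difference of -1.20 in 1 mouse and of -0.52, -0.51 and -0.39 in the others. With 135 groups, so few such values are fewer than chance alone gives.

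The difference between expanded and single-cell clones was itself compared between tissues with an interaction term in edgeR. It differed from the other tissues for 274 of 7147 genes in blood, 11 in liver, 29 in kidney, 34 in pancreas and 54 in small intestine. In liver the genes with the smallest p were the pancreas genes Cela1 and Clps, and then Bcl2. Of the 274 genes in blood, 149 had a higher difference there. Within a tissue, 957 genes separated the 2 classes in blood, 310 in liver, 6 in kidney, 114 in pancreas and 292 in small intestine.

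The CD69 antibody tag was outside the planned comparisons. Its median count was 99.6 ± 19.9 in small intestine, against 25 ± 26.1 in blood, 14.8 ± 2.99 in liver, 30.2 ± 12.4 in kidney and 18.8 ± 2.75 in pancreas (SD, n = 4). Small intestine exceeded blood in 4 of 4 mice (log2 difference 2.37 ± 1.21, two-sided exact sign-flip p = 0.13, the smallest possible). Cd69 transcripts were not highest there, at 309 CPM in kidney, 335 in pancreas and 269 in small intestine.

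Identical paired receptors in different mice were not part of a planned comparison either. Of 6140 receptors, 93 were found in 2 or more mice, in 384 cells (5.03% of the typed cells). Separate matches of the 2 chains as the whole cause are argued against by the second chain: receptors of 2 mice with the same TRB shared their TRA in 68.2% of 151 pairs, against 0.00232% of pairs with other TRB chains. That baseline takes the chains to pair at random, which selection of the same receptor in both mice would break. Independent recombination was therefore not decided. Of 107 receptors with the same amino acids in 2 mice, 14 (13.1%) differed in nucleotides. Reads moved between libraries by index exchange would carry the same cell barcode into both mice, and 0 of the 93 receptors had such a barcode. Cells carried over between samples of the same tissue stay open, since the overlap between mice was higher for the same tissue than for different tissues in 6 of 6 pairs of mice, a result that other causes could also give. The labels give no group that would test a biological explanation, and none was tested.

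Residency genes were higher in tissues than in blood, and so was the stress signature. In cells low in stress genes, residency genes outside the stress list kept a median log2 difference of 1.503 (1.86 in all cells). Of these genes, 19 of 23 were called. The rise was thus not confined to cells with a high share of stress-list UMIs. The stress list fell from 1.26 to 0.16, as choosing cells by that list brings about. Of the residency list only Dusp1 is on the stress list, and immediate-early genes such as Nr4a1 remain. Dissociation stress as the whole cause was therefore not decided. Unequal depth is argued against by thinned sums, in which 22 of the 25 residency genes called were still called. Tissue, which the design names, stays open together with handling, in part or as the whole cause. A tissue and its handling cannot be told apart in this design.

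Liver shared clones with blood almost as cells within a tissue do. The cell cycle list had a median log2 difference of 0.959 between liver and blood, with 30 of 32 genes called. This argues against a liver sample made of blood cells alone, since such cells would carry the blood profile. The difference was taken over all liver cells. It cannot show where the shared clones came from, since their cells were not tested apart. Wrong hashtag calls stay open: the overlap was 0.908 among cells whose top tag held at least 95% of the tag counts (0.906 in all), but this removed only 37 of 7628 typed cells and so hardly tests them. A mixture of blood cells and liver cells stays open too, as does exchange of cells between liver and blood. The sort for cells not reached by the intravenous antibody would lower the first where it worked, which was not tested.

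Tissue labels were redrawn within each mouse 100 times, the real labels included, to see how often as many genes are called. For liver against blood 3 of 100 draws reached the real count of 1105 (highest other draw 2784), for kidney 3 reached 2766 (highest 3910), for pancreas 2 reached 2874 (highest 3886), for small intestine 1 reached 5375 (highest 2336) and for the mean of the tissues 2 reached 3396 (highest 4288). Against the other tissues, 1 draw reached the real count in liver (5346, highest other 762), 1 in kidney (1777, highest 1160), 2 in pancreas (1570, highest 1738) and 1 in small intestine (5336, highest 8). For genes called in all 4 tissues, 2 draws reached 209 (highest 1834). Draws that call more genes than the real labels point to a structure of the samples: in 11 of the draws the small intestine sums of 3 or more mice fell under the same label, and outside these the highest count was 1090 for pancreas against blood and 19 for genes in all 4 tissues, but still 1910 for liver and 2991 for kidney against blood. For the clone contrasts the 2 class labels were instead swapped at random in each pair of mouse and tissue, again in 100 draws with the real labels included. For expanded against single-cell clones 1 draw reached 964 (highest other 107). The pairs come from 4 mice and can share clones, so they are not independent and this rank can be too low. For multi-tissue against single-tissue clones the real count was 0 (highest other 25). Any draw reaches a count of 0, so the draws cannot decide about chance there. For the other contrasts the share of draws lay under 0.05. The tissue labels were redrawn over blood and all tissues at once, so a redrawn group mixed sums of different tissues. For the contrasts of tissues a low share therefore shows only that some tissues differ. It cannot decide about chance for a given contrast, such as liver against blood.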

How the results depend on the processing

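Some settings were chosen after seeing the data. These were cells low in stress genes, no clusters led by other-cell-type genes, a 95% hashtag share and no receptors of several mice. The other alternatives were fixed in advance. Several alternatives change the depth: sums thinned to the smallest total of 647213 UMIs hold fewer UMIs, and cells low in stress genes number 83 in pancreas and 173 in small intestine. Of 242 values of comparisons under alternatives, 192 stayed within 1.5 times or 1 SD and 50 moved.

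Without the mouse block, liver against blood called 479 genes and 103 were called in all 4 tissues. With mouse and tissue as separate terms, multi-tissue against single-tissue clones called 2. Among named genes, Foxp3 in the mean against blood (0.17), Sell in liver against blood (-0.84), and Defa21 (-2.79) and Clps (1.92) in pancreas against the other tissues lost their call without the block. The call of Sell in liver was also lost without mouse 2 (-0.77), without mouse 4 (-0.79) and by DESeq2 (-0.85). The block changed no other call of a named gene and no other count of calls by more than 1.5 times. Leaving out each mouse in turn gave 347 to 993 genes for liver, 1891 to 2443 for kidney, 2107 to 2562 for pancreas and 4391 to 5024 for small intestine against blood, and 2364 to 2998 for the mean. Against the other tissues it gave 4411 to 4891 for liver, 1161 to 1512 for kidney, 1006 to 1274 for pancreas and 4338 to 4884 for small intestine. Genes called in all 4 tissues ranged from 62 to 219, expanded against single-cell clones from 567 to 853 and multi-tissue against single-tissue clones from 0 to 7. Of the 1105 genes called in liver against blood, 340 were still called without mouse 2 and 836 without mouse 3.

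The stricter cell filter gave 733 genes for liver against blood and 132 in all 4 tissues, and the cause was not tested. Thinned sums gave 345, 1299, 1445 and 2885 genes for liver, kidney, pancreas and small intestine against blood, 1617 for the mean, 2570, 859, 812 and 2917 against the other tissues, and 70 in all 4. Cells low in stress genes gave 504, 831, 317 and 1553 against blood, 920 for the mean, 1664, 249, 120 and 1273 against the other tissues, and 16 in all 4. In both settings the sums hold fewer UMIs, and the latter also selects cells, so its lower counts cannot be put down to depth alone. In it, 68.3% of the calls in kidney against the other tissues were rises, and 63.7% in small intestine. For multi-tissue against single-tissue clones DESeq2 called 1 and the fit without the low-count filter 117, and the cause was not tested. Without receptors of 2 or more mice the expanded share in liver was 11.7%, since these receptors are left out of it.

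With an estimated correlation, the number of list calls was 7 for liver, 7 for pancreas, 8 for small intestine and 8 for the mean against blood, 7 for liver, 2 for kidney, 0 for pancreas and 6 for small intestine against the other tissues, 7 for expanded and 0 for multi-tissue clones. By fry, which tests direction only, it was 0 for multi-tissue clones.

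Of 2225 values of named genes under alternatives, 2164 kept their call and sign, 44 lost the call, 9 gained it and 8 reversed. Of the 44 lost, 19 were in cells low in stress genes and 7 in thinned sums. The sign reversed in cells low in stress genes for Egr1 in kidney against the other tissues (-0.78) and for Il1rl1 in the mean against blood (-0.64). In cells with TRB it reversed for Defa21 in pancreas (0.22) and small intestine (-0.31) and for Lyz1 in small intestine (-0.14), and the cause was not tested. Cd69, never called in these contrasts, was -0.0195 in thinned sums for liver against blood, and between -0.104 and 0.0406 for expanded clones with each mouse left out. Without the low-count filter, 59.1% of the genes in all 4 tissues and 38.8% of those in expanded clones were rises.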

Other observations

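The restriction of the clone mate test to clones of 2 or more cells was chosen after its first result was seen, and the measure of the CD69 tag was added after the files were seen.

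It was asked whether cells of a clone share an expression profile beyond that of their tissue. Single-cell clones have no clone mates, so the answer cannot show why expanded cells differ from them. In 2072 cells of multi-cell clones, the expression deviations of clone mates in the same tissue, over 1000 genes without receptor genes, had a mean correlation of 0.0389, against -0.0091 when clone labels were shuffled within mouse and tissue (highest of 1000 shuffles -0.0011). Clone mates in different tissues had a mean correlation of 0.0352 against 0.0001 (highest shuffle 0.0049). Both had a one-sided permutation p of 0.001, the smallest that 1000 shuffles can give. The correlations are small, and shared lineage, shared antigen and shared activation were not told apart. Among all 7628 typed cells the values were 0.0724 and 0.0624, where expanded and single-cell clones also differ.

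A hypothesis from the CD69 protein was that cells of expanded clones also seen in blood carry less of the tag in tissues. The median tag count was lower in such cells in 9 of 12 pairs of mouse and tissue with at least 5 cells per class, with a median log2 difference of -0.246 over the 12 pairs. Over mice, the mean log2 difference was -0.549 ± 0.201 (SD, n = 4), below 0 in 4 of 4 (two-sided exact sign-flip p = 0.13, the smallest possible). This may reflect cells that arrived recently, which these data cannot date.

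Receptors seen in another mouse were more frequent among multi-cell clones (50 of 682, 7.33%) than among single-cell clones (141 of 5556, 2.54%). This difference was not tested, nor was the number of cells per clone as a source of it. Of 107 receptors with the same amino acid sequences in 2 mice, 14 (13.1%) differed in nucleotides. Without the receptors found in 2 or more mice, the overlap of blood and liver was 0.860.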
